A study of Mus musculus with 10 samples.

How the data were processed

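The data were RNA-seq read counts per gene from 10 mouse liver samples, 5 from the floxed control group (flox) and 5 from the group labelled as a knockout of Acss2 in liver cells (HKO). All had been kept on a diet rich in fat and fructose for 4 months, per the labels. The labels give no batch, sex, litter or cage, and do not state that each sample came from a separate animal. The p-values below therefore measure the spread between these samples.

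The authors isolated total RNA and prepared libraries with a VAHTS Universal V6 kit, per the labels' protocols. The values deposited by the authors were raw counts of reads per gene, whole numbers that had not been divided by library size. The submitters' processing notes name the mm10 build and DESeq2. The aligner, the counting program, the annotation, the handling of reads that match several places and the use of strand are not given in the sources used here. Coordinates are printed as the deposited table gives them, and their build is uncertain. Of 56748 gene identifiers in the table, 52073 were found in GENCODE M21, which is on GRCm38 (the assembly behind mm10), and 2.83% of those had the same start and end there. Gene symbols came from the deposited table itself, which pairs them with the identifiers. Transferrin, fixed in the hepatocyte list as Tf, is listed in the table as Trf.

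Total counts per library ran from 15413648 to 19275358, so 3 counts, the limit used for a gene with no count, were worth 0.156 to 0.195 CPM (a gene's counts scaled to a common library total), before TMM scaling. Of the genes in the table, 28040 had no count in any library and 14068 passed the filter on low counts (filterByExpr by group) and were tested. The limits from counts cover counting error only, while the confidence interval of Acss2 comes from the edgeR fit and covers the spread between libraries. Every pair of libraries within a group differed by far more than sampling noise. The smallest chi-square per degree of freedom was 24.6 over genes with at least 20 counts in the pair, so no pair within a group looked like 1 library counted more than once. Libraries prepared separately from 1 animal could differ in this way too, and treating each library as its own sample is an assumption.

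From the counts, HKO was compared with flox by the two-sided quasi-likelihood F-test of edgeR 4.0.16 with TMM normalisation, in R 4.3.3. Values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. An "edgeR adjusted p" is a value from this test. Levels are TMM-scaled CPM, given as mean ± SD with n = 5 per group unless said otherwise, and log2 fold changes are HKO over flox with their standard error (SE). The SE was calculated back from the F-test, as the absolute log2 fold change over the square root of F. The confidence interval of Acss2 uses this SE. Log2 CPM used a prior count of 2. Single values and list scores were compared by exact two-sided permutation tests over all 252 assignments of 5 and 5 libraries, whose smallest p is 0.00794.

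Gene lists for 37 pathways and cell types, the rule for named genes and the alternatives were fixed before the data were examined. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, and Benjamini-Hochberg adjusted over those lists. Camera with the correlation estimated per list and fry were run beside it. Of the 18 lists past the threshold with the preset correlation, 0 passed with an estimated correlation and 10 passed fry. A list score is the mean of its members' log2 CPM after centring each member over the 10 libraries. Cell type markers in whole tissue describe transcripts, not cell numbers.

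The genes named were chosen by the fixed rule. It took Acss2 and Aif1, then the 12 largest rises and 12 largest falls among genes with an edgeR adjusted p under 0.05, a mean of at least 1 CPM, a symbol that is not a predicted-gene name, and groups that did not overlap. It also took up to 4 members per list with the smallest p among those that passed, or up to 2 of the highest level where none did, and the first gene of each list. It named 125 genes. Genes outside it are said to have been chosen after their values were seen. The transcripts of the named genes were aligned to all GENCODE M21 transcripts with BLAST 2.17.0. Of the named genes, 23 had a near-identical copy, defined as at least 95% identity over at least 50% of the transcript, and 8 overlapped another gene with at least 10 percent of their counts.

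The gene test was tested on simulated counts for 13828 genes at the depths of this comparison, with 200 genes changed. It recovered 54% of the genes changed 2-fold and 89% of those changed 4-fold, and 13 of its 162 calls (8.02%) were false. A planted list was found by camera and fry, and 0 of 20 unchanged lists were called. The simulated genes varied independently of each other, while members of real lists can vary together (estimated correlation 0.64 for macrophage markers). False calls of lists whose members vary together were therefore not tested.

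The alternatives were DESeq2 1.42.0, other scaling factors (median-of-ratios, upper quartile, library totals alone), other filters on low counts, robust dispersion, the replicate number as a block, 1 surrogate variable (sva 3.50.0), other thresholds, a test against a 1.2-fold change, and leaving out each library in turn. All were fixed at the same point as the lists. Figures were drawn with matplotlib 3.10.9. A second deposited table, which holds gene annotation without sample values, was not used.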

Results

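Liver transcriptomes were measured in mice on a high-fat, high-fructose diet, a model of metabolic dysfunction-associated steatohepatitis, with 5 libraries from floxed controls (flox) and 5 labelled as a knockout of Acss2 in liver cells (HKO). The design asks what the loss of ACSS2, the enzyme that turns acetate into acetyl-CoA in the cytosol and nucleus, does to the liver under this diet, and the study's title points to the inflammation gene Aif1. Total counts per library ran from 16933436 to 17196774 in flox and from 15413648 to 19275358 in HKO. The 10 most abundant genes took 16.3% to 21.2% of the counts, and the lowest share was in flox replicate 5.

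Acss2 (ENSMUSG00000027605), the targeted gene, was read in every HKO library. Its level was 73.2, 86.9, 56.5, 128.8 and 58.6 CPM in flox replicates 1 to 5, and 52.8, 59.0, 43.8, 40.2 and 51.4 CPM in HKO replicates 1 to 5. The HKO mean was 61.2% of flox (95% confidence interval 44.6 to 84.0), a log2 fold change of -0.71 ± 0.21 (SE). The difference did not pass the gene test (unadjusted p = 0.00511, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0858). An exact two-sided permutation test of log2 CPM gave p = 0.0238 (n = 5 and 5). It passed under 4 alternatives, with an adjusted p of 0.0415 in DESeq2, 0.0447 in edgeR with library totals alone, 0.0433 in edgeR without a filter on low counts and 0.0460 in edgeR without flox replicate 3. Over all alternatives the adjusted p ran from 0.0415 to 0.186. Without flox replicate 4, the library with the highest level, the log2 fold change was -0.47. The gene lies on chromosome 2 from 155359868 to 155427644 on the plus strand, in the table's coordinates, whose build is uncertain. Its 3' part overlaps Gss on the other strand, which had 92.4% as many counts. The counts cover the whole gene, and which exons were deleted is not given in the sources used here, so the remaining reads check the genotype labels only weakly. Of the 11 tested neighbours of Acss2, 0 passed the gene test, with a median log2 fold change of -0.03 and a camera test, in the upward direction, that found no shift (adjusted p = 0.982).

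**Figure D1:**
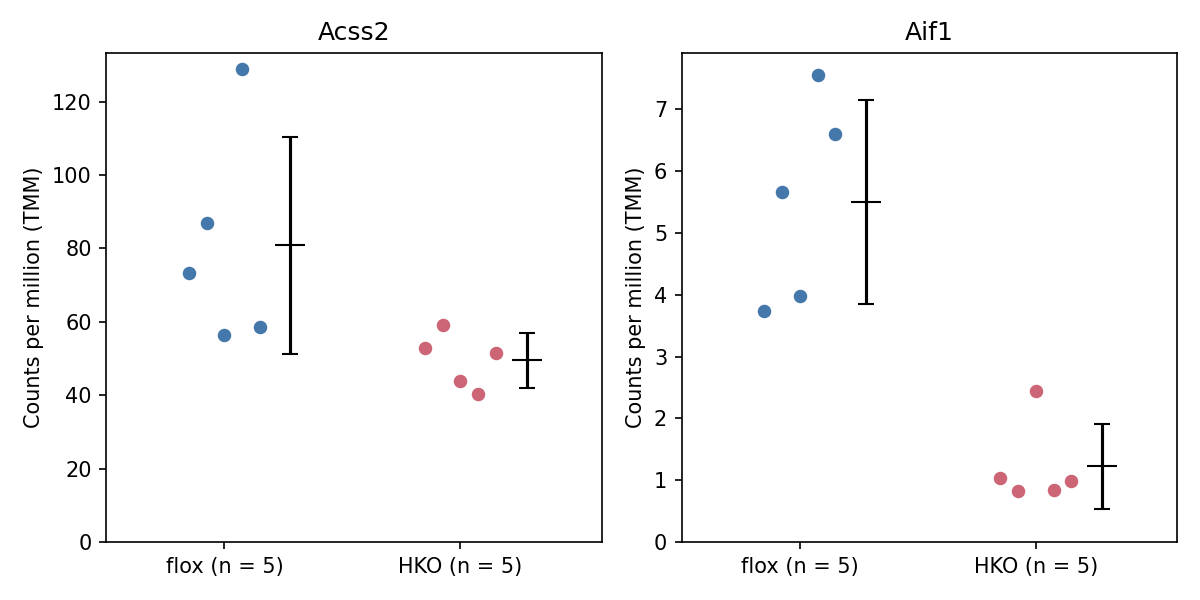
TMM-scaled CPM of Acss2 and Aif1 in each library, with the mean and SD of each group beside the points (n = 5 per group). For Acss2 the groups overlap, with flox from 56.5 to 128.8 and HKO from 40.2 to 59.0, while for Aif1 all HKO libraries (0.819 to 2.44) lie below all flox libraries (3.73 to 7.56).

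Most measured macrophage markers were lower in HKO than in flox livers (21 of 23 called), as were 7 of 16 antigen presentation genes and 8 of 21 genes of fatty acid and triglyceride synthesis, while 7 of 13 male-biased liver genes were higher. As whole lists these 4 passed camera with a preset correlation and not with an estimated one (adjusted p = 0.136, 0.181, 0.178 and 0.134 with an estimated correlation). They also passed fry (adjusted p = 0.00552, 0.0198, 0.0105 and 0.00552 in the same order). Fry asks whether a list's own genes differ, and not whether they differ more than other genes. The macrophage gene Aif1 fell 4.49-fold, the fatty acid synthase gene Fasn fell 3.10-fold and the female-biased cytochrome gene Cyp2b9 fell 175-fold, while the male-biased Mup20 rose 3.48-fold. Of 14068 genes tested, 561 passed the edgeR test at an adjusted p under 0.05, 129 higher and 432 lower in HKO, and 431 of them differed at least 2-fold. In 450 of the called genes all 5 HKO libraries lay on one side of all 5 flox libraries. Among all tested genes 5.37% were separated in this way, against 0.794% by chance. Leaving out flox replicate 5 left 361 called genes, and leaving out HKO replicates 1, 4 or 5 left 335, 289 and 354. DESeq2 called 1112, 560 of the 561 among them.

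Aif1 (ENSMUSG00000024397), which encodes a calcium-binding protein of macrophages, fell from 5.51 ± 1.65 CPM in flox to 1.23 ± 0.688 in HKO (mean ± SD, n = 5 each). The log2 fold change was -2.17 ± 0.34 (SE) with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.00621, and the exact permutation test gave p = 0.00794, the smallest it allows. The level rests on 490 counts in flox and 97 in HKO. The gene lies on chromosome 17 from 35389967 to 35395044, in the table's coordinates, whose build is uncertain.

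The fall of Aif1 came with that of other macrophage transcripts. Of 23 measured macrophage and Kupffer cell markers, 21 fell, 0 rose, and 2 did not pass, while 22 fell when adjusted over the list alone. The median log2 fold change was -1.61, and 2 of the 22 other markers had a larger fall than Aif1. Adgre1, which encodes F4/80, had a log2 fold change of -2.18 ± 0.39 (edgeR adjusted p = 0.0106). The complement gene C1qb fell from 37.8 ± 13.2 to 11.6 ± 3.89 CPM, and Csf1r, the receptor that keeps macrophages alive, from 51.0 ± 23.1 to 15.04 ± 3.46. The pore-forming Mpeg1 fell from 116.8 ± 35.6 to 36.6 ± 10.3 CPM. Csf1r overlaps Hmgxb3 on the other strand, which had 32.4% as many counts. Camera placed the list below other genes (adjusted p = 1.04e-22), but not with an estimated correlation (adjusted p = 0.136). The macrophage score was highest in flox replicates 4 and 5 (1.27 and 1.45) and ran from 0.12 to 0.54 in the other flox libraries and from -1.25 to -0.20 in HKO. Without flox replicate 5, 15 markers fell, as many as without HKO replicates 2, 4 or 5.

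Some markers of lipid-associated and monocyte-derived macrophages were also lower, with 5 of 14 falling (11 adjusted over the list alone) and a median log2 fold change of -1.78, which was -0.88 without flox replicate 5. Atp6v0d2, a subunit of the proton pump of lysosomes, fell from 14.2 ± 5.13 to 2.56 ± 1.02 CPM, and the monocyte gene Ly6c2 from 2.33 ± 1.28 to 0.482 ± 0.238. Camera gave an adjusted p of 8.57e-07 for the list, which became an adjusted p = 0.181 with an estimated correlation. The list's score stood at 1.80 in flox replicate 5 and at 0.19 to 0.32 in the other flox libraries, and 2, 3, 3 and 2 markers fell without HKO replicates 1, 2, 4 and 5.

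Of 24 genes of inflammatory cytokines and signalling, 5 fell (10 adjusted over the list alone), among them Aif1 itself and the chemokine gene Cxcl9, which went from 18.4 ± 8.63 to 6.98 ± 1.81 CPM. The list's median log2 fold change was -0.73 (camera adjusted p = 2.27e-09, adjusted p = 0.144 with an estimated correlation). It fell to 2 or 3 called genes without flox replicates 1 or 5 (3 and 2) or without HKO replicates 1, 2, 4 or 5 (2, 2, 2 and 3). Of 16 antigen presentation genes, 7 fell (13 adjusted over the list alone), with a median of -0.93 (camera adjusted p = 1.96e-09, adjusted p = 0.181 with an estimated correlation). Cd74, the invariant chain of MHC class II, had a log2 fold change of -2.14 ± 0.45 (edgeR adjusted p = 0.0183, but 0.0509 without HKO replicate 4 and 0.0529 with robust dispersion) and of -1.30 without flox replicate 5, and Psmb9, a subunit of the immunoproteasome whose gene overlaps Tap1, fell from 26.7 ± 5.14 to 13.3 ± 3.95 CPM. The antigen presentation score was 1.35 in flox replicate 5 and at most 0.53 in any other library, and the count of fallen genes was 3 without flox replicate 2 and 2, 3, 1 and 2 without HKO replicates 1, 2, 4 and 5.

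Interferon-stimulated genes had a median log2 fold change of -0.40 with 1 of 25 falling (4 adjusted over the list alone), the GTPase gene Gbp2 (-1.56 ± 0.29). Camera gave an adjusted p of 0.000155, and the adjusted p = 0.511 with an estimated correlation. Without HKO replicate 3, whose interferon score was 0.49 against -0.27 or less in the other HKO libraries, the median was -0.72 and 7 fell, and without flox replicates 1 or 3, 2 fell. Of 24 acute-phase genes, 2 fell (4 adjusted over the list alone), Lcn2, which encodes an iron-sequestering lipocalin (149.9 ± 81.2 to 26.4 ± 22.1 CPM), and Orm3 (21.3 ± 19.3 to 3.40 ± 0.998). Saa1, the classical acute-phase gene, had a log2 fold change of 0.14 ± 0.78 that rests on HKO replicate 4. Without that library it was -1.66 (edgeR adjusted p = 0.0916), and the gene is nearly identical to Saa2. The acute-phase list had a camera adjusted p of 0.0134 (adjusted p = 0.593 with an estimated correlation), 0.103 without flox replicate 1 and 0.0996 without HKO replicate 2. Without HKO replicate 4, 4 of its genes fell.

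Few markers of other liver cell types were called. Of 20 hepatocyte markers 0 passed the gene test over all genes, 2 rose adjusted over the list alone, and 2 rose over all genes without flox replicate 4. Their median log2 fold change was 0.21, or 0.10 without flox replicate 5 (camera adjusted p = 0.00519, adjusted p = 0.511 with an estimated correlation). Alb, which encodes albumin, had a log2 fold change of 0.16 ± 0.21. Of 15 sinusoidal endothelial markers, 1 fell, the cadherin gene Cdh5 (-0.87 ± 0.20), with a list median of -0.34 (camera adjusted p = 0.0114, adjusted p = 0.593 with an estimated correlation). The camera call was lost without flox replicate 3 or HKO replicates 1 or 4 (adjusted p = 0.0588, 0.0754 and 0.0825, with medians of -0.15, -0.19 and -0.14), and the median was -0.51 without HKO replicate 3. The Cdh5 call was lost without flox replicates 4 or 5 or HKO replicates 1, 2 or 4 (edgeR adjusted p from 0.0569 to 0.0722). Of 13 stellate cell and fibroblast markers, 1 fell, the intermediate filament gene Vim (28.8 ± 10.3 to 12.1 ± 3.75 CPM), and the camera adjusted p was 0.316. None of 9 cholangiocyte markers passed (camera adjusted p = 0.792), nor did any of 5 dendritic cell markers (0.798; 1 fell adjusted over the list alone, and Bst2 passed without flox replicate 1 or HKO replicate 3, edgeR adjusted p = 0.0397 and 0.0462), 6 red blood cell markers (0.100, but 0.0362 and 0.0477 without flox replicates 3 and 4) or 4 neutrophil markers. The red blood cell median of 0.20 became -0.03 without flox replicate 5 (camera adjusted p = 0.641), the library with the lowest score (-1.91). The neutrophil markers were all lower in HKO with a median of -1.001, 1 of them fell adjusted over the list alone, and Csf3r passed without HKO replicate 3 (edgeR adjusted p = 0.0163). Of 11 markers of T, NK and B cells, 1 fell, the immunoglobulin light chain Igkc (-1.62 ± 0.40), whose edgeR adjusted p of 0.0381 rose to between 0.0698 and 0.0950 without flox replicates 3, 4 or 5 or HKO replicates 1, 2, 4 or 5. The lymphocyte list itself had a camera adjusted p of 0.217, and 0.0234 without flox replicate 2. Of 27 genes of fibrosis and extracellular matrix, 1 fell, the cytokine gene Tgfb1 (-1.24 ± 0.30), with a median of -0.42 (camera adjusted p = 0.00138, adjusted p = 0.550 with an estimated correlation). Without flox replicate 5, which had a fibrosis score of 1.14 against at most 0.21 elsewhere, the list median was -0.16, the camera adjusted p was 0.0599 and that of Tgfb1 in the edgeR test 0.0864. The Tgfb1 call was also lost without flox replicate 4 or HKO replicates 1, 2, 3 or 4 (edgeR adjusted p from 0.0541 to 0.0831). Col1a1, the main fibrillar collagen, had a log2 fold change of -2.20 ± 0.69 (edgeR adjusted p = 0.0970). It was -0.86 without flox replicate 5 (edgeR adjusted p = 0.356), the library with the highest level, and -2.49 without flox replicate 4 (0.0344).

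**Figure D2:**
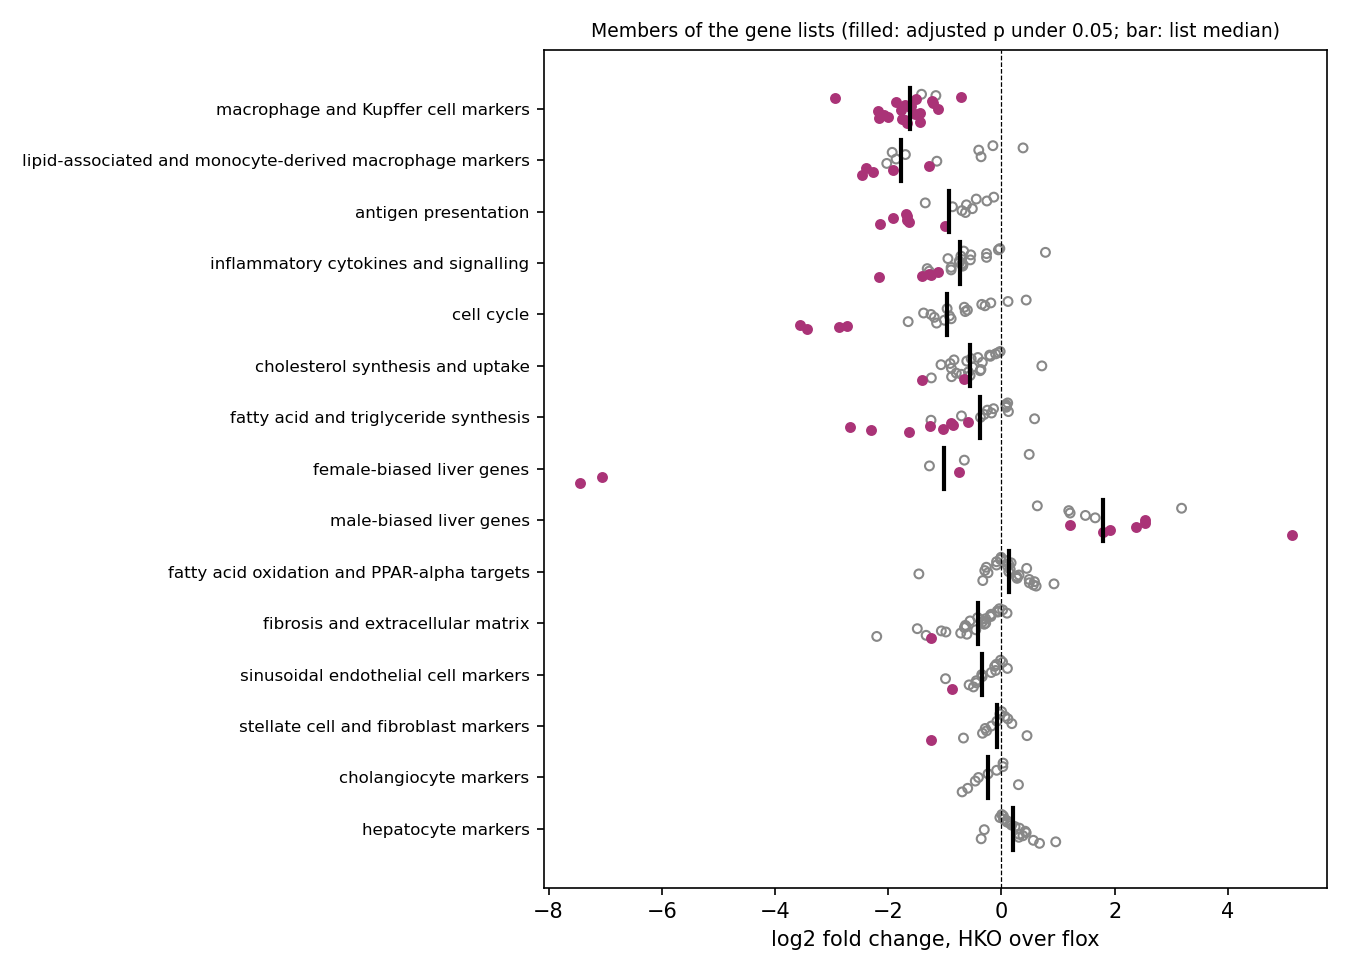
Log2 fold changes (HKO over flox) of the tested members of 15 gene lists. Each point is a gene, filled where the edgeR adjusted p is under 0.05, and the bar marks the list median. Macrophage markers centre on -1.61 and male-biased genes on 1.80, while hepatocyte markers lie near 0 with a median of 0.21.

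Part of the lipid synthesis genes fell. Of 21 genes of fatty acid and triglyceride synthesis, 8 fell, 0 rose and 13 did not pass over all genes, and 9 fell and 1 rose when adjusted over the list alone. Their median log2 fold change was -0.37, and -0.56 without HKO replicate 5. Fasn (ENSMUSG00000025153), fatty acid synthase, went from 249.5 ± 56.6 to 80.4 ± 20.2 CPM (log2 fold change -1.63 ± 0.21, edgeR adjusted p = 0.00217). Thrsp, a regulator of lipogenesis, went from 114.8 ± 53.2 to 23.1 ± 10.1 CPM. Acaca, acetyl-CoA carboxylase, went from 63.8 ± 18.9 to 31.3 ± 2.84 and shares sequence with a predicted copy. Scd1, which desaturates stearate, went from 8235 ± 6407 to 1285 ± 1167, a call lost with robust dispersion, with the replicate number as a block and without flox replicate 2 or HKO replicates 1, 2, 4 or 5 (edgeR adjusted p from 0.0523 to 0.0732). Srebf1, the transcription factor that drives this programme, had a log2 fold change of -1.24 ± 0.34 that did not pass (edgeR adjusted p = 0.0590), though it passed in 8 alternatives, among them DESeq2 (0.00644) and edgeR without flox replicates 1 or 3 or HKO replicate 2 (0.0487, 0.0341 and 0.0282). Camera gave the list an adjusted p of 3.80e-05, and adjusted p = 0.178 with an estimated correlation. The count was 3, 4 and 4 without flox replicates 2, 4 and 5, and 5, 4, 4, 4 and 3 without HKO replicates 1 to 5.

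Few genes of cholesterol synthesis and uptake passed one by one. Of 25, 2 passed the test over all genes and both fell, while 12 fell when adjusted over the list alone. The median log2 fold change was -0.55 (camera adjusted p = 1.18e-06, adjusted p = 0.178 with an estimated correlation). Without flox replicate 2 or HKO replicate 3, 4 passed. Acat2, which joins acetyl-CoA units in the cytosol, went from 48.4 ± 8.17 to 30.6 ± 0.721 CPM and is nearly identical to Acat3 in part of its transcript. Srebf2, the regulator of this pathway, had a log2 fold change of -0.38 ± 0.13 that did not pass (edgeR adjusted p = 0.142). Among 22 genes of acetate and acetyl-CoA metabolism, 4 fell (6 adjusted over the list alone), Acaca, Acat2, Acss3 (-1.69 ± 0.40) and the ATP-citrate lyase gene Acly (-0.85 ± 0.21). Camera did not place the list below other genes (adjusted p = 0.0548, and 0.511 with an estimated correlation). It did so in 8 alternatives. These were the fits without flox replicates 3 and 4 and HKO replicate 1 (0.00975, 0.0285 and 0.0289), and cameraPR (0.0147). The others were no filter on low counts (0.0254), library totals alone (0.0304), 1 surrogate variable (0.0395) and at least 1 CPM in 5 libraries (0.0445). The count of fallen genes was 2 without flox replicates 1, 2 or 5 or HKO replicates 2 to 5. The Acss3 and Acly calls were lost in most fits that left out 1 library, with edgeR adjusted p up to 0.0837 for Acss3 (without flox replicate 2) and 0.108 for Acly (without flox replicate 5).

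Most genes of lipid uptake and storage did not pass. Of 24, 3 fell and 0 rose (6 and 1 adjusted over the list alone; camera adjusted p = 0.250). Vldlr, a receptor for triglyceride-rich lipoproteins, fell from 17.3 ± 5.93 to 2.79 ± 0.752 CPM (log2 fold change -2.63 ± 0.29, edgeR adjusted p = 0.000947). The fatty acid transporter gene Cd36 fell from 314.2 ± 171.6 to 70.03 ± 26.0 CPM. The lipid droplet coat gene Plin2 had a log2 fold change of 0.81 ± 0.27 that did not pass (edgeR adjusted p = 0.121). Of 27 genes of fatty acid oxidation and PPAR-alpha targets, 0 passed, and the list median of 0.13 (0.01 to 0.26 with 1 library left out) had a camera adjusted p of 0.0135 (adjusted p = 0.605 with an estimated correlation), lost without flox replicates 3 or 4 or HKO replicates 1 or 4 (0.0891, 0.403, 0.0522 and 0.0718) and with cameraPR (0.0668). Of 21 genes of glucose and fructose metabolism, 1 fell, the pyruvate kinase gene Pklr (-1.27 ± 0.30). The Pklr call was lost without flox replicates 2, 4 or 5 or HKO replicates 2 to 5 (edgeR adjusted p from 0.0547 to 0.0754). The list's camera adjusted p was 0.0623, and 0.0473, 0.0199 and 0.0403 without flox replicate 3 and HKO replicates 1 and 5.

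Several sex-biased liver genes shifted towards the male form. Of 13 male-biased genes, 7 rose (12 adjusted over the list alone) and all 13 were higher in HKO, with a median log2 fold change of 1.80. Serpina4-ps1 rose from 3.76 ± 4.65 to 132.3 ± 92.2 CPM (5.13 ± 0.73, edgeR adjusted p = 0.00375), the urinary pheromone gene Mup20 from 686.9 ± 392.5 to 2393 ± 699.9, and the fatty acid elongase gene Elovl3 from 57.7 ± 32.5 to 218.5 ± 134.7. Of 6 measured female-biased genes, 3 fell (3 adjusted over the list alone). Cyp2b9 (ENSMUSG00000040660, chromosome 7, 25872836 to 25910086 in the table's coordinates, build uncertain) fell from 330.0 ± 197.8 to 1.86 ± 1.77 CPM (-7.45 ± 0.80, edgeR adjusted p = 0.000913), Cyp2a4, a steroid hydroxylase gene that is nearly identical to Cyp2a5, from 25.8 ± 32.7 to 0.188 ± 0.183, and Fmo2 from 28.3 ± 3.76 to 16.8 ± 3.83, a call lost without flox replicate 5 or HKO replicate 4 (edgeR adjusted p = 0.0633 and 0.0519). Camera gave an adjusted p of 4.17e-14 for the male-biased list and 0.00133 for the female-biased list, and with an estimated correlation the adjusted p = 0.134 for each. The male-biased count was 4 and 3 without flox replicates 1 and 5, and 4 without HKO replicates 1 or 4. Flox replicate 4 lay nearest to HKO, with a male-biased score of 0.40 against -2.12 to -1.25 in the other flox libraries and 0.96 to 1.58 in HKO. Before TMM scaling, Xist was at most 0.646 CPM and the tested Y-linked genes at least 15.5 CPM in every library.

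**Figure D3:**
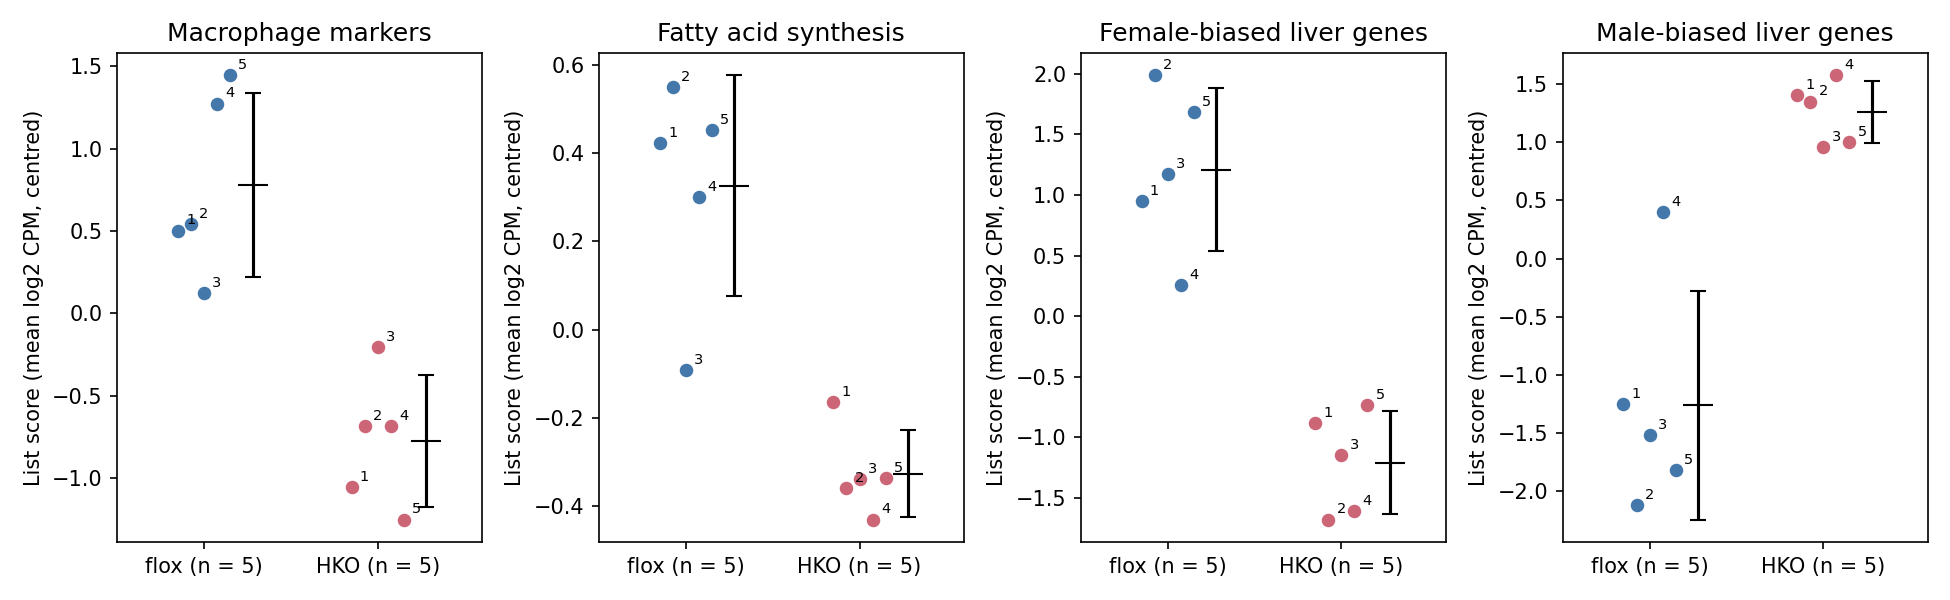
Scores of 4 gene lists per library (mean of the members' centred log2 CPM), with the mean and SD of each group (n = 5) and the replicate number beside each point. The groups did not overlap in any of the 4, and flox replicate 4 was the flox library nearest to HKO for the female-biased (0.25) and male-biased (0.40) lists.

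Major urinary protein genes filled most of the 12 largest rises under the naming rule. Mup15 had a log2 fold change of 8.17 ± 1.38, Mup13 of 6.64 ± 1.31, Mup14 of 4.57 ± 0.70, Mup11 of 4.26 ± 0.84, Mup18 of 3.94 ± 0.63, Mup1 of 3.37 ± 0.69 and Mup9 of 3.13 ± 0.76. Without HKO replicate 1, which held most of its reads, Mup13 had a log2 fold change of 4.06. These genes have up to 15 near-identical copies each, so the split of reads between them is uncertain. Summed over the 22 Mup genes, the level was 4469 ± 3521 CPM in flox and 27310.0 ± 5937 in HKO, 6.11-fold higher, with no overlap (exact permutation p = 0.00794, n = 5 and 5, the smallest it allows). The sum was chosen after the rises of single Mup genes were seen, so it is not independent of them. The Mup1, Mup11 and Mup13 calls were lost with robust dispersion (edgeR adjusted p = 0.0603, 0.0649 and 0.0702) and that of Mup9 with robust dispersion, with the replicate number as a block and without flox replicates 2, 3 or 5 or HKO replicates 1, 2, 4 or 5 (0.0516 to 0.100). Beside these and Serpina4-ps1, the 12 largest rises held the pseudogene Gtpbp4-ps1 (3.40 ± 0.36, with near-identical copies), the zinc transporter gene Slc30a3 (3.16 ± 0.36), Ces4a (2.63 ± 0.47) and the mitochondrial tRNA gene mt-Ti (2.60 ± 0.56), which overlaps the far more abundant mt-Nd1.

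Under the naming rule, the largest falls after Cyp2b9 and Cyp2a4 were those of the hydroxyacid oxidase gene Hao2 (-6.58 ± 0.73, edgeR adjusted p = 0.000947) and Cyp2a22 (-4.82 ± 0.60). The ubiquitin-like gene Ubd (-4.47 ± 1.06, but -2.40 without flox replicate 5) was called, but not with robust dispersion, with the replicate number as a block or without flox replicate 5 or HKO replicates 1, 2, 4 or 5 (edgeR adjusted p from 0.0541 to 0.104). The organic anion transporter family genes Slc22a29 (-4.33 ± 0.62), Slc22a27 (-4.19 ± 0.41) and Slc22a26 (-3.95 ± 0.48) fell together, and the first 2 are nearly identical in sequence. Pls1 (-4.30 ± 0.78), Cyp2b10 (-3.60 ± 0.80), the topoisomerase gene Top2a (-3.44 ± 0.49) and the glutathione transferase gene Gstm3 (-3.41 ± 0.48) completed the list. The Cyp2b10 call was lost with the replicate number as a block and without flox replicate 2 or HKO replicates 1, 2 or 4 (edgeR adjusted p from 0.0526 to 0.0662).

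**Figure D4:**
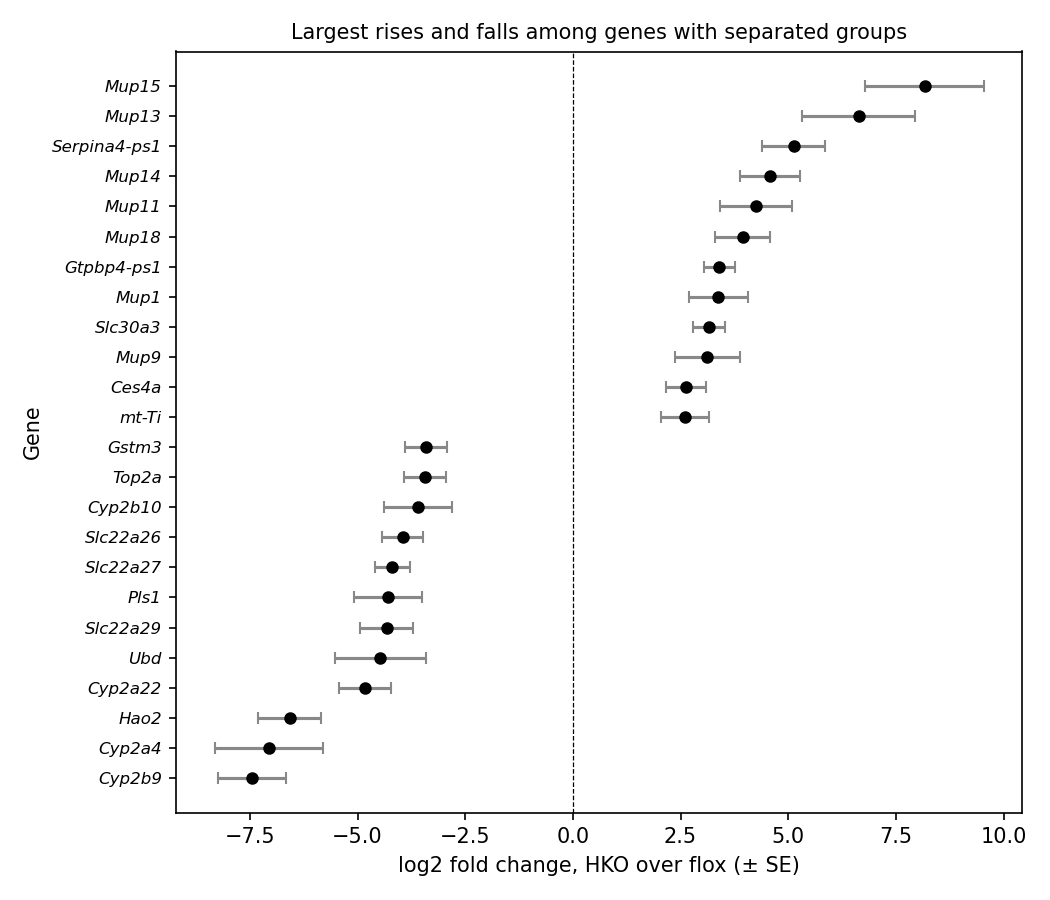
Log2 fold change (HKO over flox, ± SE) of the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, by the fixed naming rule. Mup15 is at 8.17 and Cyp2b9 at -7.45.

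Some proliferation transcripts were lower in HKO. Of 21 cell cycle genes, 4 fell (9 adjusted over the list alone), with a median log2 fold change of -0.96 (camera adjusted p = 2.62e-09, adjusted p = 0.134 with an estimated correlation). Mki67, the classical proliferation marker, fell from 8.69 ± 3.23 to 1.19 ± 1.13 CPM (-2.87 ± 0.47, edgeR adjusted p = 0.00745) and Top2a from 4.41 ± 2.72 to 0.405 ± 0.303. The count was 2 without HKO replicates 1, 2 or 4 and 7 without flox replicate 3. The cell death list had 1 member of 21 that fell (3 fell and 1 rose adjusted over the list alone), Pmaip1, which encodes the pro-apoptotic protein NOXA (-1.96 ± 0.37), and a camera adjusted p of 0.00519 (adjusted p = 0.134 with an estimated correlation). None of 11 genes of senescence and DNA damage passed (1 fell adjusted over the list alone; camera adjusted p = 0.0166, adjusted p = 0.385 with an estimated correlation, and 0.0899 without flox replicate 5).

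Some bile acid and drug metabolism genes were called, while neither list passed camera. Of 20 bile acid genes, Cyp7b1, an oxysterol hydroxylase of the alternative pathway, rose from 53.98 ± 16.9 to 249.7 ± 63.7 CPM (2.21 ± 0.22, edgeR adjusted p = 0.000841), and the uptake transporter gene Slco1a1, also a member of the male-biased list, had a log2 fold change of 2.53 ± 0.58. Abcc4, an export pump gene, had one of -2.26 ± 0.54, and camera found no shift of the list (adjusted p = 0.586). The Slco1a1 call was lost with robust dispersion and without flox replicates 1, 3 or 5 or HKO replicates 1 or 4 (edgeR adjusted p from 0.0503 to 0.0849). That of Abcc4 was lost with the replicate number as a block and without flox replicates 2 or 5 or HKO replicates 2 to 5 (edgeR adjusted p from 0.0623 to 0.0900). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of -0.60 ± 0.82, which was 0.20 without flox replicate 4 and -1.21 without HKO replicate 1. Of 22 xenobiotic metabolism genes, 6 fell and 0 rose (8 and 1 adjusted over the list alone), among them Gstm2 (74.4 ± 31.1 to 20.4 ± 9.21 CPM) and Cyp2a5 (721.5 ± 269.4 to 305.1 ± 82.9), with a camera adjusted p of 0.129 (0.0263 and 0.0412 without flox replicate 5 and HKO replicate 5). The count was 3 without flox replicate 2 or HKO replicates 1, 2 or 4.

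The remaining lists held few or no called genes. Of 12 mitochondrially encoded respiratory chain genes, 1 rose, mt-Nd3 (0.71 ± 0.18), and all 12 were higher in HKO with a median of 0.30, or 0.46 without flox replicate 1 (camera adjusted p = 0.000318, adjusted p = 0.434 with an estimated correlation). The mt-Nd3 call was lost with library totals alone (edgeR adjusted p = 0.0839) and without flox replicates 2 to 5 or HKO replicates 1, 3 or 5 (0.0514 to 0.0923). The nuclear genes of the chain did not shift (0 of 27, camera adjusted p = 0.316, but 0.0136 without flox replicate 2). Of 17 oxidative stress genes, 1 fell, Nqo1 (-1.05 ± 0.23; list camera adjusted p = 0.135), a call lost without HKO replicates 2, 4 or 5 (edgeR adjusted p = 0.0504, 0.0599 and 0.0565). No gene passed among 22 of the unfolded protein and integrated stress response (camera adjusted p = 0.0622), 20 of the circadian clock (0.403) or 15 immediate-early genes (0.0665), nor among the 3 tested markers of pancreas, adipose tissue and gut, whose median (0.43) and mean (-0.15) differ in sign. Camera placed the stress response list above other genes without flox replicates 1, 3 or 5 or HKO replicates 1 or 2 (adjusted p from 0.00256 to 0.0480), and the immediate-early genes below them without flox replicates 1, 2 or 4 or HKO replicates 3 or 5 (0.00343 to 0.0470). The lower immediate-early level rested on flox replicate 5, with a score of 1.82 against at most 0.34 elsewhere. Leaving that library out moved the list median from -0.74 to 0.01 (camera adjusted p = 0.847).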

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

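The number of called genes was compared with other splits of the libraries by a test set before the result was seen, and the other tests in this part were chosen after it was seen. Of the 126 ways to split the 10 libraries into 5 and 5, 100 were drawn, the real one included, and 1 of them, the real one, gave as many as 561 called genes, while the highest of the others gave 5. This argues against chance assignment of the libraries to groups as the source of that count. A share of 1 in 100 was the smallest that the draw could give. The score comparisons below are exact two-sided permutation tests, 14 in number, given with Benjamini-Hochberg adjusted values.

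Acss2 itself was 61.2% of flox in HKO (95% confidence interval 44.6 to 84.0), although the libraries are labelled as its knockout. A single wrong label would place a library among the other group, and 0 libraries lay on the other group's side of the first principal component, which argues against it. That component follows expression of all tested genes and does not read the genotype. Acss2 was at 40.2 to 59.0 CPM in every HKO library, so its remaining level does not rest on a single library. Reads from exons left in place, or from liver cells that kept the gene, cannot be told apart from a knockout of low efficiency with 61.2% remaining, since the counts cover the whole gene and no reads per exon were used. The overlap with Gss on the other strand, which had 92.4% as many counts, adds to this. The use of strand is not given, so whether Gss reads were counted for Acss2 was not tested. Acss2 is also a target of the factors that drive sterol synthesis, and its difference between groups (-0.65) was close to that of the cholesterol score (-0.53). The difference of Acss2 minus that score was -0.124 (exact permutation p = 0.563, adjusted p = 0.607), so the reads may have fallen with the sterol genes and not by deletion, a hypothesis that stays open beside the others.

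Of 23 macrophage markers 21 fell in HKO, and a higher share of hepatocyte RNA would lower the markers of all other cell types alike. The macrophage score minus the mean score of endothelial, stellate and cholangiocyte markers differed by -1.34 (exact permutation p = 0.00794, the smallest it allows, adjusted p = 0.0222), which argues against that explanation as the whole cause. Flox replicate 5 alone is also argued against, since 15 markers fell without it. Whether Aif1 fell more than the other macrophage markers stays open, as its log2 CPM minus their score differed by -0.602 (exact permutation p = 0.0476, adjusted p = 0.0741). Fewer macrophages in HKO and lower transcription in the same number of macrophages, both biological candidates that the genotype could bring about, were not separated by any test here.

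Several sex-biased genes shifted towards the male form in HKO. Female livers among the libraries are argued against by Xist, which was at most 0.646 CPM before TMM scaling in any library, beside Y-linked genes at 15.5 CPM or more on the same scale. Reads shared between Mup copies would leave their sum unchanged, and the log2 of the summed Mup CPM differed by 2.99 (exact permutation p = 0.00794, the smallest it allows, adjusted p = 0.0222). Stronger growth hormone signalling in HKO stays open and untested: the score of Igf1, Socs2, Cish and Onecut1 was higher by 1.27, but these genes were picked after their values were seen, so it decides nothing. Igfals, another target of the hormone that the score left out, had a log2 fold change of 0.16 (edgeR adjusted p = 0.750).

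Single libraries stood far from the rest of their group in 23 of 328 groups tested by the gap to the nearest library over the range of the group, where chance gives about 1 in 20 (16.4). In flox replicate 5 the high values were the scores of lipid-associated macrophage markers (a gap of 0.92 of the range), of glucose and fructose metabolism (0.839) and of cholangiocyte markers (0.741), and the levels of Clec7a (0.88), Vim (0.863), Gbp2 (0.753), Cd74 (0.741) and Lgals3 (0.717). In flox replicate 4, Slc22a26 (0.873), Slc22a27 (0.786) and Cyp2b9 (0.72) were low and Cyp7a1 was high (0.774). In flox replicate 1 the score of mitochondrially encoded genes was high (0.783) and that of dendritic cell markers low (0.766), and in flox replicate 2 Ces4a was low (0.719). In HKO replicate 3, Ccnb1, read in that library and at 0 in the others, was high (1), as were Vcam1 (0.822), Aif1 (0.792) and the inflammatory score (0.733), while Hba-a1 was low (0.722). In HKO replicate 4, Cyp7b1 (0.89), Ddx3y (0.787) and Ppara (0.72) were high.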

How the results depend on the processing

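No called gene or list in the text reversed under the alternatives run, which were all planned. Counts could only grow, shrink or stay. The estimated correlation, fry and cameraPR keep the list medians of the main fit, so these settings could not reverse a list. The number of called genes, 561 (129 higher, 432 lower), was 1112 (315 higher, 797 lower) with DESeq2, which tested more genes, 82 (26 and 56) at an adjusted p under 0.01, 2372 (854 and 1518) at an unadjusted p under 0.05 and 356 (74 and 282) against a 1.2-fold change. Without a filter on low counts 214 were higher. The cause was not tested. Leaving out 1 library, which lowers the number of samples, gave 289 to 673 called genes, 69 to 160 higher and 220 to 522 lower. With the replicate number as a block, 448 were called, 394 of them among the 561. The labels do not say whether the numbers pair samples. Deviations from the group means correlated at -0.121 to 0.240 between flox and HKO libraries of the same number. Each flox library correlated more with an HKO library of another number, which cannot settle whether the samples were paired. Scaling by library totals alone moved the median log2 fold change of all genes from 0.00827 to -0.0994, with 667 called. Of these calls 14.4% were higher in HKO, against 23.0% with TMM scaling. Acss2 passed with DESeq2 (-0.70), library totals alone (-0.80) and no filter (-0.70), and its log2 fold change ran from -0.81 to -0.47 when 1 library was left out. The cause was not tested. Aif1 kept its call in all alternatives (-2.57 to -2.03 with 1 library left out). Of 18 lists past the threshold, 0 passed with an estimated correlation and 10 passed fry, which tests another question. Leaving out 1 library gave 16 to 21. CameraPR, run on the signed square root of F, lost the fatty acid oxidation list (adjusted p = 0.0668). It added acetate and xenobiotic metabolism (0.0147 each), lipid droplet and lipid transport (0.0391) and glucose and fructose metabolism (0.0449). It also added the stress response (0.0327) and immediate-early lists (0.00941). Of 123 other named genes, 86 stayed on the same side of the threshold under all alternatives, 29 lost their call under at least 1 and 8 gained one. The limma test on the authors' normalized values was not run, as no such table was among the files used. In simulated data at this depth 54% of genes changed 2-fold were recovered, so smaller changes can be missed.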

Other observations

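The groups and genes in this part were chosen after their values were seen. Of 8 immunoglobulin genes, 4 fell in HKO and 4 did not pass, and no set test was run. Among those that fell were the heavy chain genes Ighg2c (-3.01, edgeR adjusted p = 0.0104) and Ighg2b (-2.35, edgeR adjusted p = 0.0219). Guanylate-binding protein genes, which respond to interferon gamma, fell in 5 of 11 cases, and glutathione transferase entries of the mu class in 5 of 8. The latter falls include that of a pseudogene, Gstm2-ps1 (-1.32, edgeR adjusted p = 0.0257). Mitochondrial tRNA genes rose in 5 of 15 cases, such as mt-Tp (1.06, edgeR adjusted p = 0.00699) and mt-Tc (1.59, edgeR adjusted p = 0.00978).

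Igfbp2, which encodes a binding protein of insulin-like growth factors, rose (log2 fold change 1.29, edgeR adjusted p = 0.00618), as did the growth factor receptor gene Egfr (1.64, edgeR adjusted p = 0.0133) and Nlrp12 (1.25, edgeR adjusted p = 0.00123). The growth hormone receptor gene Ghr had a log2 fold change of 0.01 (edgeR adjusted p = 0.989). Nsl1, a kinetochore gene, had 87 counts over the flox libraries (12 to 26 in each) and 0 in HKO. It was at least 26.3-fold lower on the TMM scale, with 3 counts over the group as the limit, on chromosome 1 from 190795209 to 190818671 in the table's coordinates, whose build is uncertain.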
